A study of Thermococcus onnurineus NA1 with 2 samples.

How the data were processed

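RNA was measured in Thermococcus onnurineus NA1 grown in MM1 medium without O2 (1 library) and in MM1 medium supplied with O2 (1 library), both in the exponential phase. Per the labels' protocols, RNA was extracted with TRIzol, treated with DNase, depleted of rRNA with a kit made for human, mouse and rat, and made into stranded libraries with an Illumina TruSeq kit. Per the labels, the submitters' processing notes name CASAVA 1.8.2, Trimmomatic 0.32, Bowtie2 2.2.4, edgeR and DESeq, with no role given for any of them. The genome build in those notes is a mouse build, which cannot hold the genes of this archaeon, so no coordinates are given. The program that counted reads per gene is not given in the sources used here, nor is whether it used the strand, so reads from overlapping or antisense genes may be shared between them.

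Each library has its own deposited table, assigned to its library by the name of the workbook sheet, which is the title of the sample, and the direction of every ratio rests on this. The tables were joined by the feature number. The deposited read counts per gene are whole numbers, per the file headers total and unique reads, and the 2 columns were equal in every row. The deposited RPKM values were made by the authors. Compared with gene lengths in the reference table, they fit reads per unit of sequencing depth (the summed reads) and per kilobase of a length shortened by 162 bases in the library without O2 and by 159 bases in the library with O2. The deposited FPKM columns hold a lower and an upper value around the RPKM, a median of 1.93 and 1.99 Poisson standard errors of the count away. Each of the 1929 genes is listed in 2 rows with the same values, and 1 was used. The tables sum to 10747525 reads without O2 and 10280150 reads with O2, with 102 and 108 genes under 100 reads. A gene with 0 reads could hold a share of up to 2.79e-05% without O2 and 2.92e-05% with O2, from a limit of 3 counts. Reads carry no molecular identifiers, so all intervals and limits cover counting error only.

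The 2 tables gave different names to 54 of the 1929 features, each of which shared its RPKM with another feature in 1 of the tables or in both. The name was taken from the table in which the RPKM was not shared, for 26 features from the O2 table and for 26 from the other, and the other 2 were left without a name, as were 2 features that both tables give the same shared name, 4 in all. Of 48 renamed features with a reference length for both names, the kept name lay within 5% of the length implied by reads and RPKM in 45 cases and the other name in 4. Product names come from the annotation column of the tables. They are not used here for 137 features with masked text and for 30 that were left without a name or named from the table without O2, since the text used is that of the O2 table. Names were checked against a table of 2057 reference genes (assembly ASM1836v1), in which 1849 of the names were found as locus tags.

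All results use log2((RPKM with O2 + 1)/(RPKM without O2 + 1)) for the 1912 genes with an RPKM of at least 10 in at least 1 library. rRNA and tRNA were not analysed here. The planned order of values put the authors' values normalised between libraries first, and RPKM was next, so RPKM is the main value. Printed folds are ratios of RPKM with no pseudocount, with exact conditional binomial 95% intervals of the counts. On the log2 scale with a pseudocount the difference of a low gene is understated. With 1 library per condition no test was made. Gene lists were fixed by patterns on product names, so a list can hold a gene whose name only mentions the function. Its median was set among 10000 random lists of the same size, matched in 10 bins of mean log2 expression, and the percentile describes these 2 libraries only. Runs are at least 3 neighbours in gene order past 2-fold in the same direction, and were set among 10000 random orders. The strand of the genes was not used, so a run need not be transcribed together.

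The gene lists, the alternatives except where said, and the rule for the genes to be named were set before the data were examined. Named genes are the 12 highest and 12 lowest ratios among genes with an RPKM of at least 50 in either library, up to 4 members of each list with the largest ratio either way, the 5 most abundant protein-coding genes of each library, and the first, last and most changed gene of each run, 177 genes in all. The text names part of them, and says where it names others. The alternatives tried were pseudocounts of 0.1 and 10, no filter, a mean RPKM of at least 50, centring on the median, the FPKM bounds, counts scaled by edgeR's TMM and by DESeq2's size factors, rescaling without the 10 most abundant genes, fold thresholds of 1.5 and 4, intervals that exclude 2-fold, longer runs and more abundant features.

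The steps were tested on simulated data, Poisson counts for 1909 genes with 200 changed by known folds. Genes changed 3-fold and 5-fold were called in 100% of 50 and 100 cases, genes changed 1.5-fold in 0% of 50, and 0 of 1709 unchanged genes were called. The counting intervals held the true fold in 94.3% of genes, 10 of 10 planted runs were found, and 1 of 100 random lists of unchanged genes lay outside percentiles 2.5 and 97.5. The simulated counts varied by counting error alone, with no difference between cultures and no unchanged neighbours that vary together. These rates therefore do not show how often real cultures, or lists that hold neighbours, give false calls. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9 was used, and R 4.3.3 with edgeR 4.0.16 and DESeq2 1.42.0 for the scaling factors.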

Results

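Thermococcus onnurineus NA1 is an archaeon that lives at high temperature and is classed as an obligate anaerobe. The study is about better growth of this organism when O2 is added. The comparison asks how transcript levels differ between MM1 medium without O2 and the same medium supplied with 20% O2, in cells taken in the exponential phase. Each condition was measured once, as 1 library of rRNA-depleted RNA, so no difference below has a replicate check and no p-value is given. The deposited tables hold 1929 genes, with 10747525 reads in the library without O2 and 10280150 reads in the library with O2, and median reads per gene of 1521 and 1388. Ratios are of the authors' RPKM in the O2 library to that in the library without O2. Intervals in brackets are 95% exact conditional binomial intervals of the 2 read counts, which cover counting error only.

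In the O2 library, many genes of the list of ferredoxins, 2-oxoacid oxidoreductases and other ferredoxin-linked enzymes (17 of 33) were at least 2-fold higher, and many genes of ribosomal proteins (23 of 59) were at least 2-fold lower. Most of the 17 lay in the runs of neighbouring genes from TON_0582 to TON_0588 and from TON_1475 to TON_1482. Of 1912 genes with an RPKM of at least 10 in either library, 193 were at least 2-fold higher in the O2 library and 211 were at least 2-fold lower, on the log2(RPKM + 1) scale. Another 1058 genes (55.3%) lay within 1.5-fold. The median log2 ratio was -0.10, so that the typical gene was slightly lower with O2 under the authors' scaling. With the counts scaled by edgeR's TMM method this median was 0.02, a shift of the median by over 0.1, and the split became 231 higher against 161 lower, or 58.9% of the calls higher in place of 47.8%.

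**Figure D1:**
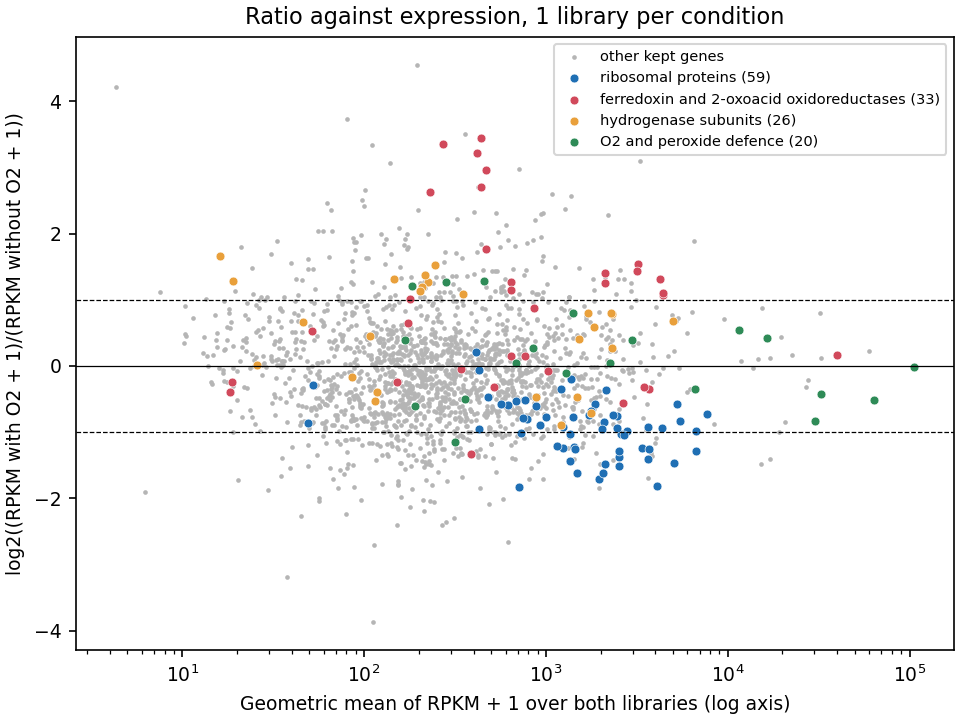
Log2 ratio of RPKM + 1 in the O2 library to that in the library without O2 (vertical axis) against the geometric mean of RPKM + 1 over both libraries (horizontal log axis) for the 1912 kept genes, with dashed lines at 2-fold. Each point is 1 gene, and most of the 59 ribosomal protein genes lie below 0 (list median -0.92) while 17 of the 33 ferredoxin and 2-oxoacid oxidoreductase genes lie above the upper line.

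The gene with the highest ratio was TON_0308, whose product name is not used here, at 39.4 RPKM without O2 and 945.7 RPKM with O2, a 24.0-fold difference (22.9 to 25.2). A block of genes annotated as subunits of 2-oxoglutarate and 2-keto acid:ferredoxin oxidoreductases, enzymes that oxidise 2-oxoacids and pass the electrons to ferredoxin, held 6 of the 12 highest ratios. Within it TON_0584 was 9.40-fold higher (8.90 to 9.93), TON_0585 was 10.97-fold higher (10.01 to 12.06) and TON_0587 was 10.3-fold higher (9.64 to 11.1). TON_0586, in the same block and with no product name used here, was 11.5-fold higher (10.7 to 12.3). Neighbours TON_1681, TON_1682 and TON_1683, of which the first and second are hypothetical proteins and the last an ATPase, were 10.4-fold, 13.9-fold and 8.49-fold higher. TON_1764, annotated as a permease of a peptide ABC transporter, stood at 24935 reads without O2 and 204489 reads with O2, which made it 8.56-fold higher (8.45 to 8.67). TON_1907, a subtilisin-type serine protease, was 7.87-fold higher (7.58 to 8.17).

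At the other end, the membrane protein gene TON_RS02825 had 121 reads without O2 and 8 reads with O2 and was 15.2-fold lower, with a wide interval (7.45 to 35.9). TON_RS01140, a hypothetical protein, was 9.78-fold lower (5.74 to 17.9). Among well-covered genes, the RNA helicase TON_1042 stood at 1550 RPKM without O2 and 244.9 RPKM with O2, a 6.33-fold lower value (6.06 to 6.61). The uncharacterised TON_0125 was 6.68-fold lower (5.92 to 7.55) and the phosphate permease TON_1552 was 5.33-fold lower (5.01 to 5.67). TON_0228, annotated as the sulfur carrier ThiS of thiamine synthesis, was 5.38-fold lower (3.712 to 7.995). TON_1437, an aspartate carbamoyltransferase of pyrimidine synthesis, was 4.98-fold lower (4.19 to 5.95), and TON_0304, a permease of the major facilitator type, was 4.795-fold lower (4.30 to 5.35).

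Genes of the translation apparatus were lower as a group in the O2 library. Of 59 genes matched as ribosomal proteins, 23 were at least 2-fold lower and 0 were at least 2-fold higher. Their median log2 ratio was -0.92, at percentile 0 among 10000 random lists of the same size matched on expression. The genes for L15e (TON_0144), S28e (TON_0953), S15 (TON_0517) and S6e (TON_1945) were 3.56-fold, 3.52-fold, 3.27-fold and 3.08-fold lower. The highest log2 ratio in this list, 0.21, belonged to TON_0698, a gene named after its values were seen, whose annotation names an acetyltransferase of ribosomal proteins and also a GMP synthase. Translation factors and tRNA ligases had a median of -0.71 over 35 genes (percentile 0), with 9 at least 2-fold lower and 0 higher. In this list the glycine tRNA ligase TON_0643 was 2.74-fold lower (2.60 to 2.88) and translation initiation factor 6 (TON_1107) was 2.67-fold lower (2.58 to 2.76). Its pattern also matched transcription factors, so the list shares genes with the next one and the 2 are not separate evidence. Shared genes include TON_0221 and TON_0342, both annotated as NusA, and the tfb gene after TON_1099, at 2.35-fold, 2.26-fold and 2.08-fold lower. RNA polymerase and general transcription factors had a median of -0.84 over 20 genes (percentile 0), of which 6 were at least 2-fold lower, among them polymerase subunits H (TON_0216) at 3.33-fold and P (TON_0454) at 2.68-fold. Nucleotide synthesis had a median of -0.56 over 21 genes (percentile 0.5), with 7 at least 2-fold lower and 2 higher. The 2 higher genes, chosen after their values were seen, were ribonucleoside-triphosphate reductase TON_1870 at 2.59-fold and TON_1871, its annotated anaerobic activating enzyme, at 3.10-fold. The CTP synthase pyrG was 4.17-fold lower (3.96 to 4.40), and TON_1438, the other gene annotated as aspartate carbamoyltransferase, was 3.15-fold lower (2.59 to 3.86).

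Ferredoxin and 2-oxoacid oxidoreductases formed the list with the most genes past 2-fold on the higher side, 17 of 33, against 1 lower, the ferredoxin:NADP reductase homologue TON_1337, which was chosen after its value was seen. Most of the 17 lay in the run of neighbours from TON_0582 to TON_0588 and in that from TON_1475 to TON_1482. The latter run has 8 genes, among them vorD and porA, and a median log2 ratio of 1.28. The median log2 ratio of the list was 1.02, at percentile 100. Besides the 2-oxoglutarate block it held the tungsten enzymes TON_1807 and TON_0444, aldehyde:ferredoxin oxidoreductases that were 3.41-fold and 2.42-fold higher, and porA next to vorD, a subunit of a 2-oxoacid oxidoreductase that was 2.92-fold higher (2.87 to 2.96). Hydrogenase subunits had a median of 0.67 over 26 genes (percentile 99.98), with 9 at least 2-fold higher and 0 lower. TON_1592 and TON_1590, annotated as hydrogenase genes, were 2.88-fold and 2.61-fold higher, and TON_1024, at 36 reads without O2 and 119 reads with O2, was 3.43-fold higher (2.34 to 5.13). Cation/proton antiporter subunits, which exchange sodium ions and protons across the membrane, had a median of 0.59 over 43 genes (percentile 100), with 11 at least 2-fold higher and 0 lower. TON_1326 was 2.43-fold higher and TON_1583 was 2.38-fold higher. The annotation of TON_1326 also names hydrogenase-4 component F, which the pattern of the hydrogenase list matches too. Genes of both kinds lay in the run from TON_1586 to TON_1595, so these 2 lists are not separate evidence. Both members of the CO dehydrogenase list were higher, TON_1018 by 3.88-fold (3.42 to 4.42) and the accessory gene TON_1019 by 2.93-fold (2.31 to 3.75). Both were weak, TON_1018 at 16.3 RPKM without O2 and 63.4 RPKM with O2, and TON_1019 at 13.5 and 39.6 RPKM.

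**Figure D2:**
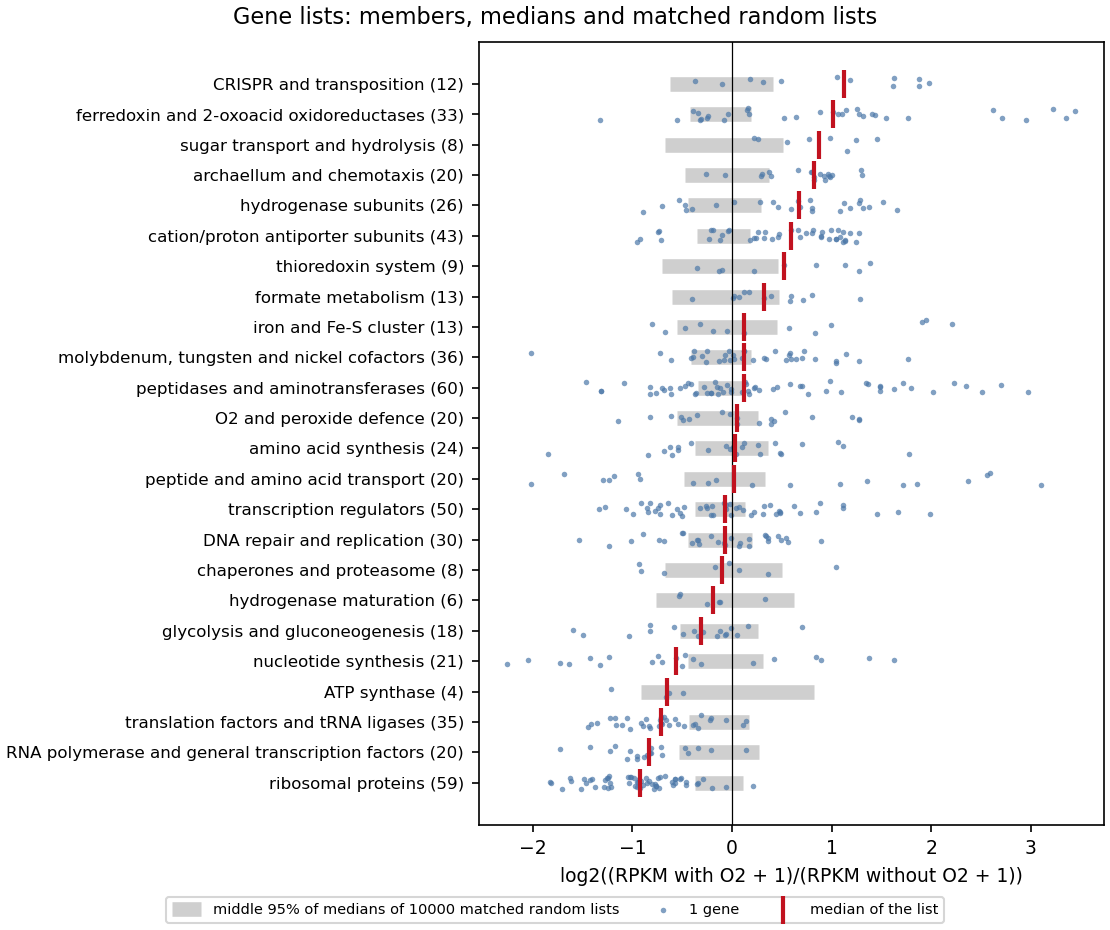
Log2 ratio of RPKM + 1 with O2 to that without O2 (horizontal axis) for the kept members of 24 gene lists, with the number of members in brackets. Points are genes, red marks are list medians and grey bars span the middle 95% of medians of 10000 random lists matched on expression, which the medians of ribosomal proteins (-0.92) and of CRISPR and transposition genes (1.12) lie outside on either side.

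Of the 20 genes of the O2 and peroxide defence list, 4 were among the 5 protein-coding genes with the highest RPKM in the library without O2. This RPKM uses a shortened gene length, which raises short genes most. Without O2, rubredoxin TON_0867 had 7622 reads at 37762 RPKM, while superoxide reductase TON_0868 had 212619 reads at 106329 RPKM. Superoxide reductase (TON_0868), which turns superoxide into peroxide, had the highest RPKM in both libraries, 106329 without O2 and 104925 with O2. Its log2 ratio was -0.02, and 0.08 when ratios were centred on the median of all genes. Peroxiredoxin TON_0829 stood at 75951 RPKM without O2 and was 1.43-fold lower with O2 (1.42 to 1.44). The alkyl hydroperoxide reductase TON_0847 was 1.77-fold lower (1.76 to 1.78) and rubredoxin TON_0867, a small iron protein that carries electrons, was 1.35-fold lower (1.30 to 1.39). The rubrerythrins TON_0864 and TON_0873 were 2.31-fold and 2.42-fold higher and the thioredoxin peroxidase TON_0862 was 2.43-fold higher. Over the 20 genes of the list 3 were at least 2-fold higher and 1 was at least 2-fold lower, TON_1271, annotated as NADH oxidase or coenzyme A disulfide reductase, at 2.22-fold. The median of the list was 0.05, at percentile 84.1 among matched random lists. In the thioredoxin system 3 of 9 genes were at least 2-fold higher and 0 were lower, with a median of 0.52 (percentile 98.4). TON_0865 was 2.62-fold higher, and its annotation names a pyridine nucleotide-disulfide oxidoreductase and also a nitric oxide reductase FlRd-NAD(+) reductase. Thioredoxin reductase TON_1603 had a log2 ratio of 1.14. The third was the peroxidase TON_0862. The SufB (TON_0850), SufD (TON_0849) and SufC (TON_0851) genes, whose proteins assemble iron-sulfur clusters, were 4.61-fold, 3.88-fold and 3.74-fold higher, while the other 10 genes of the iron and Fe-S cluster list were all under 2-fold on the log2 scale. With no pseudocount, the iron ABC transporter gene TON_0297 of this list was 2.04-fold higher (1.69 to 2.485). TON_0336, which the pattern of that list did not match, was 4.93-fold lower (4.67 to 5.21), and its annotation names an Fe-S cluster assembly protein and also 3-hexulose-6-phosphate isomerase. The list median was 0.12 (percentile 77.5), and -0.12 at a mean RPKM of at least 50.

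Genes for peptide and amino acid transport went both ways, with 8 of 20 at least 2-fold higher and 5 at least 2-fold lower. Their median was 0.02 (percentile 69.0, or 99.1 at a mean RPKM of at least 50). TON_1766, TON_1767 and TON_1768 of the peptide ABC transporter were 6.04-fold, 5.90-fold and 5.17-fold higher, and the amino acid permease TON_0640 was 4.11-fold lower (3.71 to 4.56). The other 4 lower genes, chosen after their values were seen, were the peptide transporter TON_1669, the amino acid transporter TON_0783, and TON_0158 and TON_0159 of a branched-chain amino acid transporter. Among peptidases and aminotransferases 15 of 60 genes were at least 2-fold higher and 4 were lower, namely TON_1555, TON_0651, TON_0565 and TON_0790, chosen after their values were seen. The metalloprotease genes TON_0804 and TON_0805 were 5.79-fold and 5.15-fold higher, and the 4-aminobutyrate aminotransferase TON_1605 was 6.51-fold higher. The median of that list was 0.12 at percentile 97.6, and it was -0.01 at percentile 88.3 when only genes with a mean RPKM of at least 50 were used. It was also within the upper percentile limit, which it passed in the main setting, with a pseudocount of 10 (percentile 96.6), with either FPKM bound, with TMM and DESeq2's size factors, and when rescaled without the 10 most abundant genes. Sugar transport and hydrolysis had 3 of 8 genes at least 2-fold higher and 0 lower (median 0.88, percentile 99.6), namely alpha-amylase TON_1660 at 2.24-fold, the sugar transporter gene TON_1791 at 2.37-fold and amylopullulanase TON_1792, an enzyme that breaks down starch and pullulan, at 2.75-fold (2.69 to 2.81). In glycolysis and gluconeogenesis 3 of 18 genes were at least 2-fold lower and 0 were higher, the fructose-bisphosphate aldolase TON_0903 by 3.04-fold, phosphoglycerate kinase TON_0990 by 2.86-fold and phosphoenolpyruvate carboxykinase TON_0192 by 2.05-fold (list median -0.32, percentile 18.6).

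CRISPR and transposition genes had a median of 1.12 over 12 genes (percentile 100), with 7 at least 2-fold higher and 0 lower. Of these 7, 6 were neighbours in the run from TON_0892 to TON_0898. Random lists draw genes singly, so that neighbours that differ together make the percentile of this and other lists more extreme. Csm3 (TON_0895), Csm4 (TON_0896) and Csm5 (TON_0897), subunits of a type III CRISPR complex, were 3.99-fold, 3.73-fold and 3.72-fold higher. Archaellum and chemotaxis genes had a median of 0.83 over 20 genes (percentile 100), with 3 at least 2-fold higher and 0 lower. These 3 were the neighbours TON_1183, TON_1184 and flagellin TON_1185, the last at 2.51-fold (2.11 to 2.98). The intervals of TON_1183 (1.84 to 2.23) and TON_1184 (1.965 to 3.28) reached below 2-fold. All 3 were weak, at 50.67, 26.01 and 27.95 RPKM without O2. Formate metabolism had a median of 0.32 over 13 genes (percentile 91.1), with TON_1022 at least 2-fold higher and 0 genes lower, and the formate hydrogenlyase subunit TON_1568 was 1.74-fold higher (1.70 to 1.78). TON_1022 was weak, at 11.1 RPKM without O2 and 28.5 RPKM with O2, and its log2 ratio was 0.87 with a pseudocount of 10. Its annotation also names NADH dehydrogenase subunit 1, and it lay in a run with hydrogenase genes up to TON_1024. Genes for molybdenum, tungsten and nickel cofactors had a median of 0.12 over 36 genes (percentile 93.3), with 1 lower, TON_0258 at 4.08-fold, and 5 at least 2-fold higher. These 5 were TON_1807, TON_0444, TON_1354, TON_0690 and TON_1410, part of which were chosen after their values were seen. For hydrogenase maturation the median was -0.19 over 6 genes (percentile 43.0), with 0 past 2-fold. For the 4 genes matched as ATP synthase it was -0.65 (percentile 10.1). Of these 4, subunit I (TON_1747) alone was past 2-fold, at 2.33-fold lower. It lay in a run with its neighbours TON_1746 and TON_1748, which were 2.62-fold and 2.12-fold lower. Neither neighbour has a product name used here, so no list could hold them. Transcription regulators lay at -0.07 over 50 genes (percentile 64.8), chaperones and proteasome at -0.10 over 8 genes (percentile 55.7) and DNA repair and replication at -0.08 over 30 genes (percentile 54.0), and each of these 3 medians was above 0 with TMM scaling. Among regulators 5 genes were at least 2-fold higher, including TON_0836 at 3.99-fold and TON_1254 at 3.18-fold, and 3 were lower, including TON_0475 at 2.52-fold. The thermosome subunit TON_1877, at 172 RPKM without O2, was 2.06-fold higher. TON_0707, with the same annotation and at 1528 RPKM without O2, was 1.88-fold lower (1.84 to 1.92). The pattern of the chaperone list did not match TON_1276, annotated as a heat-shock protein and chosen after its value was seen. TON_1276 lay in the run from TON_1270 to TON_1277, whose 4 genes were all at least 2-fold lower. DNA polymerase TON_1518 was 2.36-fold lower. Amino acid synthesis lay at 0.03 over 24 genes (percentile 53.8), and at -0.13 at a mean RPKM of at least 50, with 3 genes at least 2-fold higher in the main setting (TON_0702, TON_1138 and TON_1650) and 1 lower. TON_1138 was weak, at 4.11 RPKM without O2 and 10.06 RPKM with O2. The intervals of TON_1138 (1.72 to 3.54) and TON_1650 (1.88 to 2.35) reached below 2-fold. In this list S-adenosylmethionine synthetase TON_0560 was 3.59-fold lower and the glutamate synthase small chain TON_0702 was 3.44-fold higher. The 2 genes matched as sulfur metabolism, TON_0289 and TON_1017, had log2 ratios of -0.65 and 0.53, and their median of -0.06 was 0.04 with TMM.

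Genes past 2-fold lay next to each other more often than random orders of the genes gave. There were 21 runs of at least 3 neighbouring genes that were all at least 2-fold higher, holding 98 genes, and 11 runs that were all at least 2-fold lower, holding 57 genes. In 10000 random orders the median was 2 runs in each direction, and the largest numbers were 8 and 9. The run from TON_0582 to TON_0588 held 7 genes of the 2-oxoacid oxidoreductase block, with a median log2 ratio of 3.22. From TON_1764 to TON_1771 there were 8 genes beginning with the peptide transporter, with a median of 2.35. The longest runs had 10 genes each. On the higher side this was TON_1586 to TON_1595, a hydrogenase and antiporter block with a median of 1.12, and on the lower side the run from the tfb gene after TON_1099, which encodes transcription initiation factor IIB, to rpl39e, with a median of -1.33. A run of 4 riboflavin synthesis genes from ribH to TON_0610 was higher, with TON_0609, riboflavin synthase, at 5.46-fold (4.65 to 6.45).

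**Figure D3:**
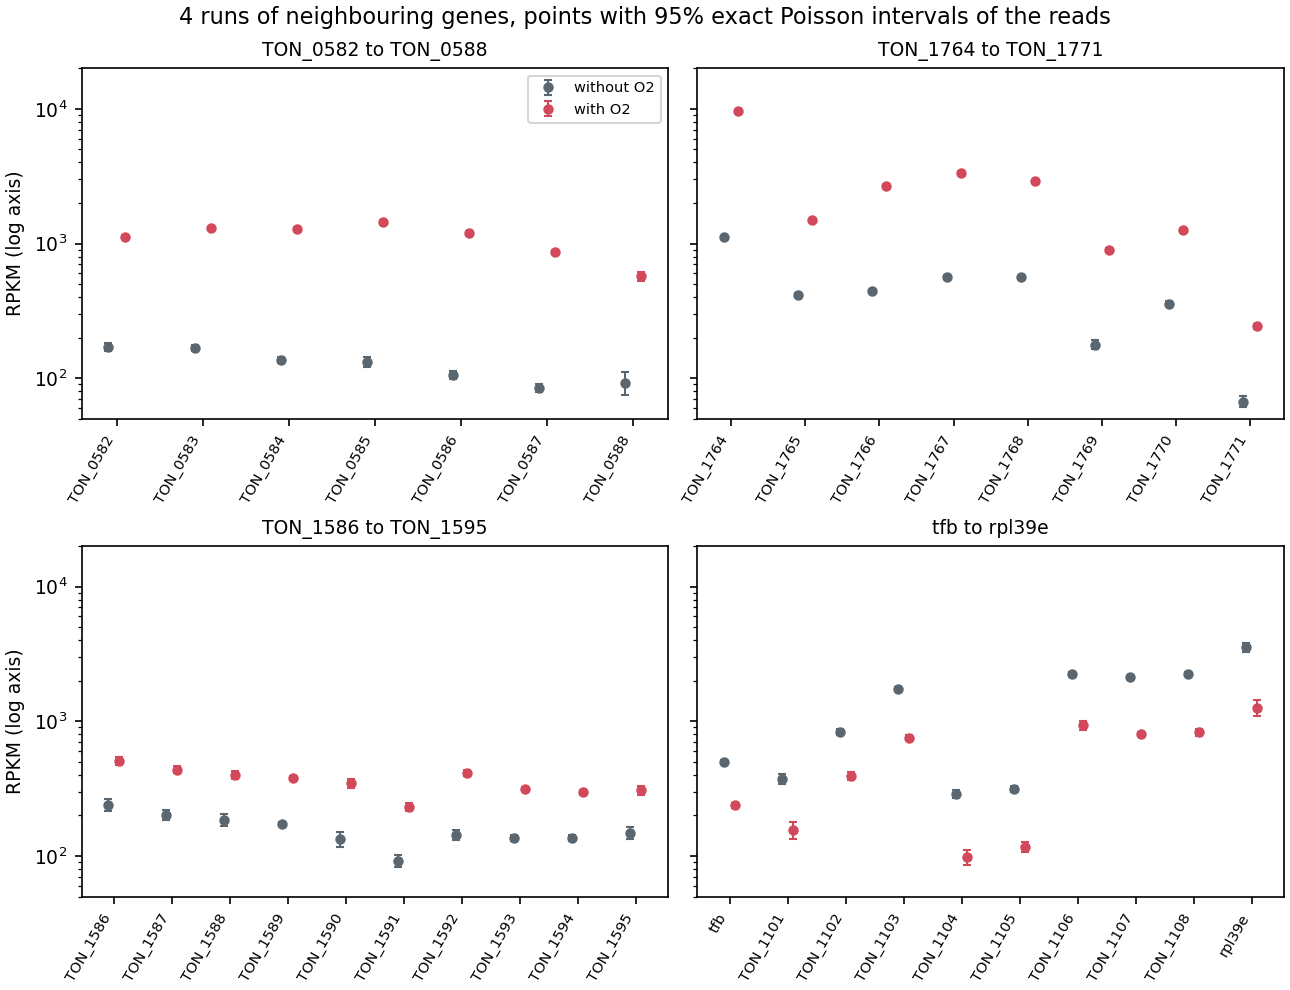
RPKM on a log axis (vertical) for each gene of 4 runs of neighbours in gene order (horizontal), grey without O2 and red with O2, with 95% exact Poisson intervals of the reads as error bars. Every gene of the runs from TON_0582, TON_1764 and TON_1586 has the higher value with O2, and every gene of the run from tfb to rpl39e has the lower value with O2.

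The 10 features with the highest RPKM held 24.8% of the summed RPKM without O2 and 24.8% with O2, while the 10 features with most reads held 25.258% of the reads without O2 (25.232% to 25.284%, exact Clopper-Pearson) and 21.875% with O2 (21.85% to 21.901%). Among the features with the highest RPKM was an RNA gene annotated as RNase P. The 5 protein-coding genes with the highest RPKM in the O2 library were superoxide reductase, peroxiredoxin TON_0829, the archaeal histone TON_0185, ferredoxin TON_1361 and the hypothetical protein TON_0747. Of these the histone was 1.73-fold higher with O2 (1.70 to 1.77), at 24529 RPKM without O2 and 42525 RPKM with O2. It had 13001 reads without O2 and 22386 reads with O2. Ranks by RPKM depend in part on the shortened length, which raises short genes most. With 1 culture per condition, a difference between cultures, harvests or library preparations would appear in these ratios in the same way as a difference with O2.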

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

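The share of the summed reads and the list without radical SAM proteins were chosen after the data were seen. No paired analysis was possible because each condition has 1 library, and no library could be left out. The count of higher genes lay between 174 and 232, and the count of lower genes between 161 and 224, under the 10 changes of pseudocount, filter or scaling. With ratios centred on their median, the 193 higher genes and 170 of the 211 lower ones were still past 2-fold. At a threshold of 1.5-fold 351 genes were higher and 503 lower, and at 4-fold 37 and 19, by construction. Requiring an interval that excludes 2-fold left 155 and 162. The median log2 ratio of -0.10 became 0.00 when centred, 0.0152 with TMM, -0.0014 with DESeq2's size factors and -0.0083 when rescaled to equal RPKM totals without the 10 most abundant genes. The shares of RPKM of these 10 genes were 0.1 points apart, so the last shift came from the equal totals. The settings with TMM and DESeq2's size factors also used counts in place of RPKM, so what they moved cannot be put down to the scaling alone: each left 190 of the 193 higher genes past 2-fold, and the antiporter median of 0.59 was 0.62 and 0.61 with them. The antiporter median fell to 0.40 at a mean RPKM of at least 50 and to 0.47 with a pseudocount of 10. The medians of the 24 lists with a percentile stayed within the 95% interval of their main value in every setting run. The median of the 2 CO dehydrogenase genes was 1.28 with a pseudocount of 10, which lowers ratios of weak genes, in place of 1.69. At a mean RPKM of at least 50, peptidases and aminotransferases, outside the percentile limits in the main setting, were at -0.0144 in place of 0.12, and iron and amino acid synthesis were also below 0 (the cause was not tested). Sulfur metabolism, regulators, chaperones and DNA repair were above 0 when centred or with TMM. DNA repair and replication was at 0.07 over 25 genes without the radical SAM proteins that its pattern caught. With runs of at least 4 genes there were 20 runs in place of 32, and at 1.5-fold there were 91. The 50 most abundant features held 46.6% of the summed RPKM without O2 and 46.1% with O2, and the 10 with most reads held 25.3% and 21.9% of the reads. Of the 149 named genes past 2-fold, 143 were still past it when centred and 138 with a pseudocount of 10. Depth limits genes with few reads, such as TON_RS02825 with 8 reads in the O2 library, and no depth replaces a replicate.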

Other observations

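The hydrogenase list, whose median was above 0, also held members with lower values in the O2 library, among them the annotated coenzyme F420 hydrogenase subunits. TON_1559, TON_1560 and TON_1561, chosen after their values were seen, were 1.63-fold, 1.86-fold and 1.38-fold lower in the O2 library. The alcohol dehydrogenase TON_0544 stood at 25571 RPKM without O2 and 9145 RPKM with O2, 2.80-fold lower (2.78 to 2.82), and the peptide transporter TON_1669 was 3.23-fold lower (3.19 to 3.27) while the peptide ABC transporter from TON_1764 was higher. These too were chosen after their values were seen.

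The patterns below were picked after gene ratios had been seen, and 3 tests, of the RPKM gain of runs, of the spread of abundant genes and of the share of reads in the most abundant features, were also chosen after the values they measure were seen at least in part. Ribosomal protein genes are short, at a median of 393 bases against 741 for all kept genes, so a length bias between the libraries might lower them. With the trend on length, fitted without the list, taken out, the list median was -0.88 (95% interval -0.99 to -0.74), which argues against length as the whole cause. Dilution by a few abundant genes needs a larger share of reads in these with O2, but the share of the 10 features with most reads was different by -3.38 percentage points with O2 (21.875% against 25.258%). The median of -0.83 after rescaling without the 10 most abundant genes decides nothing, since their shares of the RPKM were alike. A difference in growth rate or stage between the cultures, with O2 or apart from it, stays open and was not tested.

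For the runs of neighbours that were higher with O2, a length bias would have to lift their genes, but 99.0% of the 98 genes were still at least 2-fold higher with the length trend taken out. Residual genomic DNA in the O2 library could raise weak genes, and the test set in advance did not decide on it: the 192 genes with the lowest mean expression had a median log2 ratio of 0.16 (95% interval 0.07 to 0.29), between the bounds of 0.1 and 0.5. For genes of the runs that gained at least the median of 479.9 RPKM, a test chosen later argues against DNA as the whole gain. Of the 1814 genes outside the runs, 67.8% (65.6% to 70.0%) had an RPKM with O2 below that gain. The test cannot decide for weak runs, which gained far less, such as that with TON_1022, at 11.1 RPKM without O2 and 28.5 RPKM with O2. A small amount of DNA and a response of these genes to O2 both stay open, and whether a run is transcribed as 1 unit was not tested.

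The 4 genes of the defence list with the highest RPKM, TON_0868, TON_0829, TON_0867 and TON_0847, had log2 ratios from -0.82 to -0.02 (TON_0868 was at 0.08 with ratios centred), and a ceiling on ratios of abundant genes might hide a difference. Among the 191 most abundant genes, of which 9 are in the defence list, the SD of log2 ratios was 1.00 times that of all kept genes (bootstrap interval 0.89 to 1.11). This leaves a ceiling open, since most of these genes are far less abundant, and 4 genes outside the list had a mean RPKM in the range of those 4, too few to decide. Why they were abundant without O2 was not tested.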
